A study of Rattus norvegicus with 260 samples.

How the data were processed

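Poly-A RNA was measured by sequencing in 260 libraries from Sprague-Dawley rats. The dams received corn oil (vehicle), 2,3,7,8-tetrachlorodibenzo-p-dioxin (TCDD) or 2,3,7,8-tetrachlorodibenzofuran (TCDF) by gavage, and tissue was taken on gestation day 20 from dam liver, male and female fetal liver, fetal pituitary and fetal testis. The labels divide the work into 3 experimental blocks. In blocks 1 and 2a a loading dose on gestation day 6 was followed by daily maintenance doses from gestation day 7, and tissue was taken 30 minutes after the last dose. In block 2b a single dose of 10 µg/kg was given on gestation day 15. Loading doses were 0.03, 0.3 and 1 µg/kg in block 1 and 3, 6 and 10 µg/kg in block 2a. Block 1 holds all 5 tissues, blocks 2a and 2b pituitary and testis only. Doses of the text are loading doses, or the single dose in block 2b. The maintenance doses differed between the compounds at every matched loading dose: per the labels TCDD had 10 times the daily dose of TCDF in block 1 (0.22 against 0.022 µg/kg at a loading dose of 1) and TCDF had 10 times that of TCDD in block 2a (2.2 against 0.22 µg/kg at 10). They were used as the labels give them, and block 2b is the comparison in which both compounds had the same dose. An exposure field of the labels starts at gestation day 8, and the sample descriptions place the loading dose on day 6.

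Each deposited file holds raw read counts for 32545 Ensembl rat gene IDs, made by the authors with CASAVA 1.8, HISAT2 and HTSeq 0.7.2 from stranded poly-A libraries of RNA kept in RNAlater. The genome build and the annotation release are not given in the sources used here. The 5 classes of unassigned reads that end each file were kept out of the library sizes. The files give IDs only, and the rat gene table at hand (47357 genes) pairs none of them with a name (0 matches). Gene lists and genes that had been fixed by name were therefore not tested. No 2 of the 497 pairs of libraries within a group held identical counts. In 176 libraries of dam liver, fetal liver and fetal testis, genes that differ strongly between the labelled sexes of the fetal livers gave 0 libraries against their label.

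Gene counts per library ranged from 5.01 to 55.7 M reads (median 29.8), which was 6.92% to 65.0% of all reads of a library (median 48.4%). Reads that aligned to more than 1 place made up 20.0% to 85.8% (median 32.2%), and reads that were not aligned 2.86% to 13.0%. The labels deem 14 libraries outliers, and these were left out of every test: 2 of TCDD 0.3 in pituitary of block 1, 3 of the 5 vehicle pituitaries of block 2a, 1 each of TCDD 6, TCDD 10, TCDF 3 and TCDF 6 in pituitary of block 2a, 1 of TCDD 10 in pituitary of block 2b, 1 of TCDF 10 in testis of block 2b, 1 each of TCDF 0.03 and TCDD 1 in male fetal liver and 1 of TCDD 0.3 in female fetal liver. Female fetal liver at TCDF 0.03 had 1 library and was not tested against vehicle.

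Counts were analysed in R 4.3.3 with edgeR 4.0.16. Each organ and block had 1 model holding all its dose groups, with fetal livers of either sex apart, which made 9 models. Genes with low counts were removed with filterByExpr (minimum count 10, minimum total count 15), library sizes were scaled by the trimmed mean of M-values (TMM), and groups were compared with edgeR's robust quasi-likelihood F test. P-values were adjusted by Benjamini-Hochberg within each comparison, and a gene was called at an adjusted p under 0.05. The 45 comparisons of a dose with the vehicle of its block answered which genes the compound changed. A joint test over the matched loading doses of an organ and block compared TCDD with TCDF. Interaction tests compared the effects between fetal sexes in liver (male and female livers in 1 model) and between repeated dosing and the single late dose at 10 µg/kg in pituitary and testis (blocks 2a and 2b in 1 model). CPM are counts scaled to a common library total, on TMM-scaled library sizes. Standard errors and 95% intervals of log2 differences come from the fitted means and dispersions, and can be wider than the p-value of the F test implies. These p-values measure the spread between samples. Counting intervals (exact binomial, 95%) and the floor of 3 reads cover counting error only, because reads amplified by PCR without molecular identifiers are not independent molecules.

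Each test was tested on simulated data made from the same libraries with 200 changed genes. At the highest TCDD dose of each organ and block, edgeR recovered 60% to 91% of genes changed 2-fold and 77% to 99% of genes changed 4-fold, and 4.06% to 11.1% of its calls were unchanged genes. In the joint test of the compounds up to 16.5% of the calls were unchanged genes (pituitary of block 2b). The simulated genes varied independently of each other, without the shifts that genes of real libraries can share. These rates may therefore not hold for the real libraries.

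The rule for genes to name took, for the highest dose of each compound in each organ and block, up to 6 rising and 6 falling genes with the largest change among those called, with a mean of at least 1 CPM in either group and no overlap between the libraries of both groups. It had asked for a gene name. With IDs only, that demand was dropped after the data were seen, and the 2 rising and 2 falling IDs found in the most of the 18 lists are printed: ENSRNOG00000019500 (13 lists), ENSRNOG00000014721 (11 lists), ENSRNOG00000014761 (4 lists) and ENSRNOG00000022242 (2 lists). The lists held 43 rising and 58 falling IDs in all. What these genes encode is not stated, because the files do not pair IDs with names.

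Dose groups came from different dams, so litters do not pair a treated fetus with a vehicle fetus. They do pair the sexes: 22 litters, read from the dam numbers in the titles, gave livers of both sexes. Across 13649 genes, which are not independent replicates, the deviations of brother and sister livers from their group means had correlations of 0.210 to 0.624 (mean 0.344), against a mean of -0.0881 with other litters of the same treatment. A fit with the litter as a block (limma 3.58.1, voom with an estimated correlation of 0.361) was therefore an alternative for the comparison of the sexes. No other comparison can be blocked by litter.

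A set of 223 genes followed the share of unaligned reads within groups (Pearson r above 0.6 over 55 fetal liver libraries of block 1). Their mean log2 CPM is called the alignment score. A response score was made for testis and pituitary from the genes called at TCDD 10 in block 2b, without the genes of the alignment score: the mean log2 CPM of the rising genes (342 in testis, 1062 in pituitary) minus that of the falling genes (500 and 1014). It was measured in the libraries of blocks 1 and 2a, which took no part in choosing its genes, and compared by two-sided exact permutation tests with Benjamini-Hochberg adjustment over 36 comparisons and 95% intervals by inversion of the test. Groups of genes at least 8-fold higher in vehicle libraries of an organ than in the other organs were tested with camera (limma) at a preset correlation of 0.01 and with an estimated one. On simulated data camera called a changed group and 0 of 20 unchanged groups. Those genes were simulated as independent, so this does not test whether the preset correlation is high enough.

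Alternatives were DESeq2's median-of-ratios size factors in edgeR, no filter on low counts, DESeq2 1.42.0 as the test, the labelled outliers kept, only the vehicle and 1 dose group in the model, each replicate left out in turn, the litter block in limma voom, limma voom without it, a model without the genes of the alignment score, and the alignment score as a covariate. The groups, the tests, the threshold and the alternatives other than those with the alignment score and voom without the litter were chosen before the data were examined. Both scores, the organ groups, the choice of IDs, the comparisons of a group with the mean of other groups and the alternatives with the alignment score or with voom without the litter were chosen after the data were seen. For the 52 counts from groups of at least 3 libraries, other splits of the same libraries into groups of the same sizes were tested, at most 100 per comparison. The 8 counts that rest on the 2 vehicle pituitaries of block 2a had no splits.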

Results

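TCDD and TCDF both bind the aryl hydrocarbon receptor, a transcription factor that induces genes of foreign-compound metabolism. Messenger RNA was measured on gestation day 20 in dam liver, fetal liver of either sex, fetal pituitary and fetal testis after dams had received either compound or vehicle. Block 1 (loading doses 0.03, 0.3 and 1 µg/kg) covered all 5 tissues, block 2a (3, 6 and 10 µg/kg) and block 2b (a single 10 µg/kg on gestation day 15) pituitary and testis. The 260 libraries formed 55 groups, of which 9 were vehicle groups. Groups held 3 to 5 analysed libraries, except vehicle pituitaries of block 2a (2) and female livers at TCDF 0.03 (1, not tested). Gene counts per library were 19.9 to 46.8 M reads in dam liver, 16.0 to 40.8 in female liver, 15.6 to 39.8 in male liver, 5.01 to 40.2, 11.3 to 50.7 and 17.3 to 55.7 in pituitary of blocks 1, 2a and 2b, and 18.8 to 37.8, 29.1 to 40.3 and 30.0 to 39.0 in testis of these blocks. Genes are given by Ensembl ID because the files do not pair IDs with names. Doses are loading doses in µg/kg, levels are means ± SD in CPM (counts scaled to a common library total), and tests are edgeR's unless another is named.

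In dam liver the gene ENSRNOG00000019500 rose at each TCDD dose and went from near absence to a major transcript. Its level was 0.218 ± 0.121 CPM under vehicle and 3.92 ± 2.35, 295 ± 73.9 and 1506 ± 279 CPM at TCDD 0.03, 0.3 and 1 (n = 5 each). The log2 changes were 4.18 (95% interval 2.89 to 5.47), 10.40 (9.13 to 11.67) and 12.75 (11.48 to 14.02), with adjusted p = 0.000305, 9.71e-13 and 1.01e-14. TCDF raised the same gene at 0.3 and 1, to 47.4 ± 37.2 and 253 ± 65.2 CPM, by log2 7.77 (6.50 to 9.04, adjusted p = 3.64e-10) and 10.19 (8.92 to 11.46, adjusted p = 1.45e-12). At TCDF 0.03 the level was 1.11 ± 0.300 CPM and the difference of log2 2.34 was not called (adjusted p = 0.990, in DESeq2 0.0161, up to 1.00 over all alternatives). In a model of vehicle and TCDD 0.03 alone the lowest TCDD dose gave adjusted p = 0.0906, and its other alternatives went down to 6.50e-15.

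By the number of called genes, a broad response in dam liver appeared only at TCDD 1, where 1100 of 13066 genes changed, 527 up and 573 down. Of these, 18.3% changed at least 2-fold (75 up, 126 down), and the median log2 change was 0.54 among rising and -0.49 among falling genes. TCDD 0.3 and 0.03 called 5 (4 up, 1 down) and 1 (up). The 5 genes that edgeR called there became 3 without vehicle replicate 2, 3 or 4 or TCDD 0.3 replicate 1 or 5. TCDF 1 and 0.3 called 3 and 2 genes, all up, and TCDF 0.03 called 0 (529 at unadjusted p < 0.05, 1 in DESeq2). The falling genes at TCDD 1 included 80 of the 121 measured genes that follow the share of unaligned reads (median log2 change -1.73), and that share was 9.58% ± 0.973 under vehicle and 6.20% ± 0.570 at TCDD 1. The count at TCDD 1 was 537 without vehicle replicate 1, 679 without vehicle replicate 3, 366 without TCDD 1 replicate 3, 306 with vehicle and TCDD 1 alone in the model and 29 with the alignment score as a covariate.

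Against TCDF at the same loading dose, TCDD gave dam livers a higher level of ENSRNOG00000019500. The difference was 6.19-fold at 0.3 (95% interval 3.45 to 11.1, adjusted p = 0.00229) and 5.91-fold at 1 (3.30 to 10.6, adjusted p = 0.000602), and was not called at 0.03 (3.57-fold, 1.79 to 7.12, adjusted p = 0.711). The maintenance dose of TCDD was 10 times that of TCDF in these groups. With the alignment score as a covariate the difference at 1 gave adjusted p = 0.135, and its other alternatives went down to 1.66e-07. The joint test over the 3 doses called 223 of 13066 genes (544 in DESeq2). This count was 92 without the genes of the alignment score and ranged from 71 without TCDF 1 replicate 3 to 571 without TCDF 0.3 replicate 4. It was 147, 119, 147, 117, 131, 148, 86 and 87 without TCDF 0.3 replicates 1 and 3, TCDF 1 replicate 4, TCDD 0.3 replicates 3 and 5, and TCDD 1 replicates 1, 2 and 3.

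**Figure D1:**
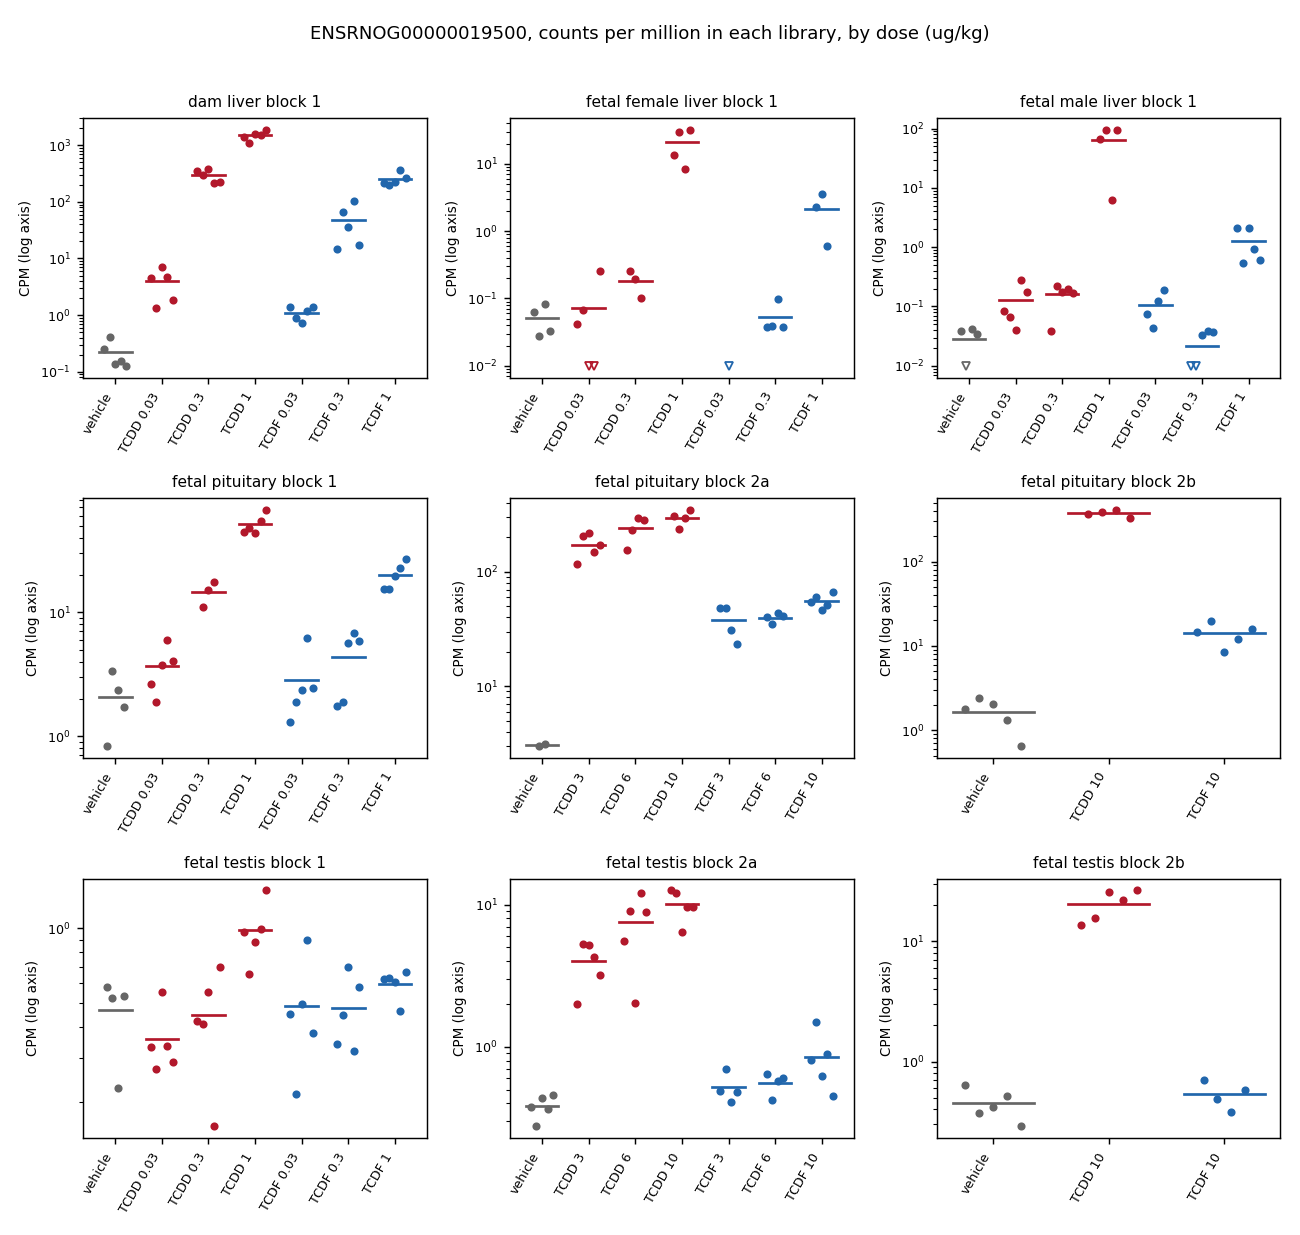
ENSRNOG00000019500 in every analysed library of each organ and block, by compound and dose. The CPM axis is logarithmic, open triangles are libraries with 0 reads, drawn at 0.01 CPM, and the highest group mean is 1506 CPM, in dam liver at TCDD 1.

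Fetal livers responded through the same gene at dose 1, at far lower levels than dam livers. In females ENSRNOG00000019500 had 6 reads in 4 vehicle livers and rose to 20.9 ± 11.7 CPM at TCDD 1 (n = 4), a ratio of 433 (95% counting interval 199 to 1183, adjusted p = 2.37e-11). In males it had 3 reads in 4 vehicle livers and rose to 64.9 ± 41.4 CPM at TCDD 1 (n = 4), a ratio of 2591 (886 to 12570, adjusted p = 9.34e-15). The counting intervals of these ratios leave out the spread between livers. At TCDF 1 ENSRNOG00000019500 rose in females to 2.14 ± 1.49 CPM (n = 3, ratio 46.8, 21.2 to 129, adjusted p = 0.00176), with adjusted p = 0.0523 without vehicle replicate 2 and 0.0986 without TCDF 1 replicate 2 (other alternatives down to 5.05e-06). In males at TCDF 1 the level was 1.25 ± 0.782 CPM (n = 5, ratio 48.2, 16.3 to 236), which was not called (adjusted p = 0.176, over the alternatives 0.000298 in DESeq2 to 0.393). At doses 0.03 and 0.3 it was at most 0.185 CPM in any group of fetal livers, and no difference from vehicle was called.

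Few other genes of fetal liver passed the test. TCDD 1 called 1 gene in females (up, 2446 at unadjusted p < 0.05, 194 in DESeq2) and 19 in males (14 up, 5 down, 2021 unadjusted, 198 in DESeq2), of 15224 and 14324 genes tested. TCDF 1 called 1 gene in females and 0 in males (1316 unadjusted, 1 in DESeq2). TCDD 0.3 called 3 genes in males and 0 in females (899 unadjusted, 1 in DESeq2, 48 with the labelled outlier kept), and TCDF 0.3 called 0 in both (1235 in females and 731 in males unadjusted, 1 and 0 in DESeq2). TCDD 0.03 called 0 in both (794 and 660 unadjusted, 0 in DESeq2) and TCDF 0.03 called 0 in males (453 unadjusted, 0 in DESeq2). On simulated counts of these livers, with genes varying independently, the test recovered 72% (females) and 75% (males) of genes changed 2-fold at TCDD 1. Recovery in the real livers was not measured. The 1 gene in females at TCDD 1 became 2 without vehicle replicate 2 and 5 and 95 without TCDD 1 replicates 2 and 3. The 1 at TCDF 1 became 0 without vehicle replicate 2 or TCDF 1 replicate 2, 2 without vehicle replicate 3 and 4 without TCDF 1 replicate 3. In females the 0 at TCDD 0.3 became 16, 7 and 11 without its replicates 1, 2 and 4. The 0 at TCDD 0.03 became 2 without vehicle replicate 2 or 4. In males the 3 genes at TCDD 0.3 became 0 without vehicle replicate 1, 3 or 4 or TCDD 0.3 replicate 1, and 1 and 5 without TCDD 0.3 replicates 3 and 4. Their 0 at TCDD 0.03 became 1 without its replicate 3. The 19 genes in males at TCDD 1 became 63, 3, 4 and 3 without vehicle replicates 1, 2, 3 and 4, became 4, 2, 144 and 3 without TCDD 1 replicates 2, 3, 4 and 5, and were 111 with the labelled outlier kept.

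TCDD at dose 1 raised ENSRNOG00000019500 above TCDF at dose 1 in fetal livers of both sexes. The difference was 9.46-fold in females (95% interval 5.22 to 17.2, adjusted p = 9.25e-06, over the alternatives 1.46e-11 to 0.0933, the latter in DESeq2) and 50.9-fold in males (26.9 to 96.2, adjusted p = 9.51e-14). The joint test of the compounds called 1 gene in females (7, 2 and 4 without TCDD 0.3 replicates 1, 2 and 4) and 2 in males (1 without any of 15 libraries, 4 without TCDF 0.03 replicate 4 or TCDD 0.03 replicate 3, 10 without TCDD 0.3 replicate 5). The effect of TCDD 1 on this gene did not differ between the sexes by the test (log2 2.42, male minus female, -2.84 to 7.68, adjusted p = 1), nor did that of TCDF 1 (log2 -0.01, -5.31 to 5.30, adjusted p = 1). These 2 values come from the model without litters, and the gene was not tested with the litter as a block. Over all genes the sex comparison called 3 genes for TCDD and 0 for TCDF (319 unadjusted, 1 in DESeq2) of 15505. In limma voom the 3 became 0, with the litter as a block and without it, with the labelled outliers kept 203, and with 1 replicate left out from 1 (male TCDD 0.3 replicate 1) to 12 (female TCDD 0.3 replicate 4).

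Fetal pituitaries of block 1 raised 2 of the printed genes and lowered 1 at TCDD 1. ENSRNOG00000019500 rose from 2.07 ± 1.06 (n = 4) to 51.2 ± 9.66 CPM (n = 5, log2 4.64, 95% interval 3.57 to 5.71, adjusted p = 7.08e-07). ENSRNOG00000014721 rose from 0.879 ± 0.101 to 15.7 ± 2.24 CPM (log2 4.16, 3.49 to 4.83, adjusted p = 1.13e-10). ENSRNOG00000014761 fell from 29.2 ± 4.73 to 5.32 ± 2.10 CPM (log2 -2.45, -3.10 to -1.79, adjusted p = 7.46e-07). At TCDD 0.03 and 0.3 its levels were 8.87 ± 2.77 and 8.10 ± 0.736 CPM (adjusted p = 0.00142 and 0.00895), and over the alternatives these p-values ranged up to 0.578 and 0.203, in models of vehicle and 1 dose alone. TCDF 1 raised ENSRNOG00000019500 to 20.0 ± 4.93 CPM (log2 3.27, 2.20 to 4.34, adjusted p = 0.000349) and ENSRNOG00000014721 to 3.90 ± 1.36 CPM (log2 2.16, 1.48 to 2.84, adjusted p = 0.000234). With vehicle and TCDF 1 alone in the model these p-values were 0.145 and 0.321, and other alternatives went down to 4.71e-11 and 1.49e-10. TCDD exceeded TCDF at 1 in ENSRNOG00000014721 (4.01-fold, 2.72 to 5.91, adjusted p = 9.59e-06) and lay below it in ENSRNOG00000014761 (log2 -1.78, -2.40 to -1.16, adjusted p = 0.000299), and the difference in ENSRNOG00000019500 was not called (2.58-fold, 1.34 to 4.96, adjusted p = 0.938).

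Beyond these, block 1 pituitaries gave short lists. The model's spread between libraries (coefficient of variation) was 26.2%, against 11.4% and 9.36% in pituitaries of blocks 2a and 2b. The median share of reads aligned to more than 1 place was 48.0%, against 27.6% and 25.3%. Short lists here therefore do not show that few genes responded. TCDD 0.03, 0.3 and 1 called 4, 2 and 9 of 17153 genes (15 in DESeq2 at 0.3 and 25 at 1), and TCDF 0.03, 0.3 and 1 called 0 (1097 unadjusted, 1 in DESeq2), 0 (557 unadjusted, 0 in DESeq2) and 3. The joint test of the compounds called 2 genes (8 in DESeq2). The 9 genes at TCDD 1 became 4, 28, 32 and 15 without vehicle replicates 1, 2, 3 and 4, and 5 without each of TCDD 1 replicates 2, 3, 4 and 5. The 4 at TCDD 0.03 became 1 and 9 without vehicle replicates 1 and 4 and 2 without TCDD 0.03 replicate 2 or 3. The 2 at TCDD 0.3 became 1 without vehicle replicate 1 and 10, 0 and 0 without TCDD 0.3 replicates 1, 2 and 5. Without vehicle replicates 2, 3 and 4, TCDF 0.03 called 1, 3 and 2 and TCDF 0.3 called 5, 4 and 4. The 2 between the compounds became 6 without TCDD 0.3 replicate 1 and 4 without TCDD 1 replicate 5.

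In block 2a pituitaries the 2 rising genes reached higher levels than in block 1, and TCDD exceeded TCDF in ENSRNOG00000019500 at each loading dose, although TCDF had 10 times the maintenance dose. ENSRNOG00000019500 was 3.08 ± 0.110 CPM under vehicle (n = 2) and 172 ± 41.1 (n = 5), 241 ± 62.8 and 297 ± 45.8 CPM (n = 4) at TCDD 3, 6 and 10 (log2 5.79, 6.28 and 6.57, adjusted p = 2.02e-08, 4.41e-09 and 1.71e-09). TCDF 10 raised it to 55.6 ± 7.90 CPM (n = 5, log2 4.17, 95% interval 2.49 to 5.85, adjusted p = 1.21e-05). TCDD exceeded TCDF 4.59-fold (2.13 to 9.90), 6.09-fold (2.71 to 13.7) and 5.26-fold (2.46 to 11.3) at 3, 6 and 10 (adjusted p = 2.15e-06, 8.53e-07 and 3.30e-07), and at 6 the alignment score as a covariate gave adjusted p = 0.0676 (other alternatives down to 3.97e-30). ENSRNOG00000014721 rose from 1.21 ± 0.411 to 79.7 ± 23.7 CPM at TCDD 10 (log2 6.03, 3.79 to 8.28, adjusted p = 3.44e-07). ENSRNOG00000014761 fell from 41.4 ± 0.0454 to 8.11 ± 3.90 CPM at TCDD 10 (log2 -2.38, -4.22 to -0.54, adjusted p = 0.00212, over the alternatives 0.000116 to 0.0520, the latter without vehicle replicate 5).

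TCDD 3, 6 and 10 called 25, 222 and 277 of 18320 genes in block 2a pituitaries (13, 98 and 92 up), and TCDF 3, 6 and 10 called 10, 6 and 44. At TCDD 10, 38 of the rising and 49 of the falling genes changed at least 2-fold. Group means of the alignment score were -0.19 at TCDD 6 and -0.18 at TCDF 10 against -1.28 under vehicle, and 19 of the 44 genes at TCDF 10 belonged to that score, all rising. Without vehicle replicate 4 the counts at TCDD 3, 6 and 10 and TCDF 10 were 6, 51, 43 and 15, and without vehicle replicate 5 they were 3, 24, 27 and 5, because 2 vehicle libraries carry all these comparisons. At TCDD 10 they were 128, 160, 476 and 132 without TCDD 10 replicates 1, 3, 4 and 5, at TCDD 6 360 and 130 without TCDD 6 replicates 2 and 5, at TCDD 3 15 without TCDD 3 replicate 2 and at TCDF 10 29 without TCDF 10 replicate 3. At TCDF 3 the count was 6 and 0 without vehicle replicates 4 and 5 and 6 without TCDF 3 replicate 3 or 4. At TCDF 6 it was 0 without vehicle replicate 5 and 10 without TCDF 6 replicate 4. With the labelled outliers kept the counts were 274 at TCDD 3, 1231 at TCDD 6 and 270 at TCDF 10. The compounds differed in 432 genes in the joint test (184 with the outliers kept, 280 without the genes of the alignment score, 848 in DESeq2).

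After the single dose of block 2b, the only pituitary comparison at fully matched doses, TCDD raised ENSRNOG00000019500 far above TCDF. Its levels were 1.65 ± 0.686 CPM under vehicle (n = 5), 373 ± 32.2 after TCDD (n = 4) and 14.1 ± 4.18 after TCDF (n = 5). The log2 changes were 7.76 (95% interval 6.87 to 8.65, adjusted p = 7.06e-14) and 3.06 (2.17 to 3.94, adjusted p = 2.30e-05), and TCDD exceeded TCDF 26.1-fold (16.7 to 40.7, adjusted p = 9.26e-13). ENSRNOG00000014721 rose after TCDD from 0.707 ± 0.520 to 120 ± 15.9 CPM (log2 7.37, 6.37 to 8.36, adjusted p = 6.07e-16) and exceeded its level after TCDF 41.8-fold (27.0 to 64.8, adjusted p = 7.05e-16). ENSRNOG00000014761 fell after TCDD from 41.4 ± 8.21 to 6.60 ± 2.71 CPM (log2 -2.73, -4.48 to -0.98, adjusted p = 0.00238, over the alternatives 9.03e-08 to 0.698, the latter with the alignment score as a covariate), and its difference after TCDF was not called (log2 -0.81, -2.33 to 0.72, adjusted p = 0.182).

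TCDD changed 2150 of 16879 genes in these pituitaries (1062 up, 1088 down) and TCDF 547 (202 up, 345 down). Changes of at least 2-fold made up 14.5% of the TCDD genes (113 up, 199 down), and 6 rising and 31 falling genes after TCDF. The compounds differed in 574 genes, 308 higher and 266 lower after TCDD. Of 170 measured genes of the alignment score 74 fell after TCDD (median log2 change -1.15) and 16 after TCDF, and unaligned reads were 8.47% ± 0.918 under vehicle, 5.59% ± 0.260 after TCDD and 6.25% ± 0.143 after TCDF. With that score as a covariate the counts were 20 for TCDD, 17 for TCDF and 53 between the compounds. The TCDD count was 1320 without vehicle replicate 3 and 1408 and 1290 without TCDD replicates 2 and 4. The TCDF count was 150, 180, 253 and 145 without vehicle replicates 1, 3, 4 and 5, 2172, 50, 180, 150 and 255 without TCDF replicates 1, 2, 3, 4 and 5, and 126 with the labelled outlier kept.

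In fetal testes of block 1 many genes differed between TCDD 1 and vehicle, by small amounts, and few were called between TCDD 1 and the other doses. Against vehicle 960 of 17570 genes were called (399 up, 561 down), of which 2.71% changed at least 2-fold (22 up, 4 down). Between TCDD 1 and the mean of the other 5 dosed groups, a comparison without the vehicle, 4 genes were called (1497 unadjusted). ENSRNOG00000014721 rose from 2.89 ± 0.314 (n = 4) to 7.14 ± 0.451 CPM (n = 5, log2 1.31, 95% interval 1.02 to 1.61, adjusted p = 1.85e-07) and exceeded its level at TCDF 1 1.70-fold (1.42 to 2.02, adjusted p = 0.00101). TCDD 0.03 and 0.3 called 12 and 216 genes, and against the mean of their other dosed groups edgeR called 0 (675 unadjusted, DESeq2 not run) and 30. TCDF 0.03, 0.3 and 1 called 228 (171 up, 57 down), 4 and 0 (1968 unadjusted, 43 in DESeq2), and the compounds differed in 19 genes. The count at TCDD 1 was 480 and 186 without vehicle replicates 2 and 3, 474 and 240 without TCDD 1 replicates 2 and 3 and 96 with vehicle and TCDD 1 alone in the model. The count at TCDF 0.03 was 103, 1, 0 and 551 without vehicle replicates 1, 2, 3 and 4 and 3, 1 and 11 without TCDF 0.03 replicates 2, 3 and 5, and that at TCDD 0.3 was 109, 49 and 7 without vehicle replicates 1, 2 and 3 and 82, 619, 17, 731 and 27 without TCDD 0.3 replicates 1 to 5. The 12 genes at TCDD 0.03 became 0, 0, 0 and 2 without vehicle replicates 1 to 4 and 0, 0, 0 and 1 without TCDD 0.03 replicates 2 to 5. The 4 at TCDF 0.3 became 0, 0, 0 and 12 without vehicle replicates 1 to 4 and 0, 0, 0, 0 and 1 without TCDF 0.3 replicates 1 to 5. The 0 at TCDF 1 became 10 without its replicate 1.

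In block 2a testes TCDD raised both rising genes and lowered ENSRNOG00000022242 with dose, and TCDF at 10 times the maintenance dose changed them less. ENSRNOG00000019500 was 0.382 ± 0.0715 CPM under vehicle and 3.99 ± 1.39, 7.52 ± 3.86 and 10.1 ± 2.48 CPM at TCDD 3, 6 and 10 (n = 5 each, log2 3.37, 4.30 and 4.72, adjusted p = 0.000705, 1.98e-07 and 4.72e-09). At TCDF 10 it was 0.854 ± 0.397 CPM (n = 5), which was not called (log2 1.15, 95% interval -0.31 to 2.62, adjusted p = 0.531). TCDD exceeded TCDF 7.61-fold (3.08 to 18.8), 13.4-fold (5.96 to 30.3) and 11.8-fold (6.23 to 22.4) at 3, 6 and 10 (adjusted p = 0.000911, 9.38e-06 and 1.13e-07). ENSRNOG00000014721 rose from 2.88 ± 0.423 to 14.3 ± 4.10, 18.3 ± 4.26 and 21.1 ± 3.07 CPM at TCDD 3, 6 and 10 (log2 2.31, 2.67 and 2.88, adjusted p = 1.34e-07, 8.73e-10 and 3.93e-11), and exceeded TCDF 3.12-fold at 10 (2.33 to 4.16, adjusted p = 4.84e-07). ENSRNOG00000022242 fell from 6.24 ± 1.02 to 2.12 ± 0.375, 1.44 ± 0.473 and 1.18 ± 0.268 CPM (log2 -1.55, -2.11 and -2.39, adjusted p = 4.10e-05, 1.49e-07 and 4.57e-09), below TCDF at 10 by log2 -1.77 (-2.31 to -1.23, adjusted p = 1.08e-05). With the alignment score as a covariate, TCDD minus TCDF at 3 changed sign in both rising genes (log2 -0.37 and -0.44, adjusted p = 0.937 and 0.824, other alternatives down to 1.13e-10 and 2.06e-10).

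TCDD 3, 6 and 10 called 35, 1008 and 2157 of 17886 genes in block 2a testes (20, 380 and 980 up), and TCDF 3, 6 and 10 called 208 (169 up, 39 down), 1 and 16. At TCDD 10, 10.2% of the genes changed at least 2-fold (180 up, 39 down). The compounds differed in 1295 genes. Of 181 measured genes of the alignment score 150 rose at TCDD 10 (median log2 change 1.08) and 110 at TCDF 3 (1.03), where a model without them called 44 genes. The group means of that score were -1.31 ± 0.085 under vehicle, -0.28 ± 0.046 at TCDD 10 and -0.33 ± 0.044 at TCDF 3. The count at TCDD 10 was 1395 without vehicle replicate 5, and that at TCDD 6 was 627 without vehicle replicate 5 and 663 without TCDD 6 replicate 4. At TCDD 3 it was 20, 22 and 17 without vehicle replicates 1, 3 and 5 and 13, 17 and 64 without TCDD 3 replicates 2, 3 and 4. The count at TCDF 10 was 10, 0, 4 and 3 without vehicle replicates 1 to 4 and 3 and 4 without TCDF 10 replicates 4 and 5. The 1 gene at TCDF 6 became 0 without vehicle replicate 2 or 5 or TCDF 6 replicate 1, 3 or 4, and 2 without TCDF 6 replicate 2.

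After the single dose, TCDD changed 879 genes of the testis and TCDF 25, and no change of the rising genes was called after TCDF. ENSRNOG00000019500 was 0.450 ± 0.136 CPM under vehicle (n = 5), 20.6 ± 5.88 after TCDD (n = 5, log2 5.49, 95% interval 4.54 to 6.44, adjusted p = 1.49e-08) and 0.537 ± 0.135 after TCDF (n = 4, log2 0.24, -1.01 to 1.49, adjusted p = 0.930). TCDD exceeded TCDF 38.0-fold (20.4 to 71.0, adjusted p = 4.94e-08). ENSRNOG00000014721 rose after TCDD from 2.87 ± 0.616 to 27.5 ± 3.35 CPM (log2 3.25, 2.90 to 3.60, adjusted p = 1.05e-10), 6.59-fold above TCDF (5.22 to 8.33, adjusted p = 1.90e-09), and ENSRNOG00000022242 fell from 6.28 ± 1.11 to 1.05 ± 0.312 CPM (log2 -2.58, -3.0 to -2.16, adjusted p = 2.54e-08, over the alternatives 1.97e-46 to 0.372, the latter with the alignment score as a covariate). The 879 genes of 17499 tested were 343 up and 536 down (61 and 36 at least 2-fold), and the 25 were 7 up and 18 down. Of these, 37 of the 879 and 15 of the 25 belonged to the alignment score, and the compounds differed in 276 genes (124 higher, 152 lower after TCDD). The TCDD count was 585 without TCDD replicate 2, 71 with the labelled TCDF outlier kept and 10 with the covariate. The TCDF count was 16 without vehicle replicate 3 or TCDF replicate 2, and the count between compounds was 167 and 172 without TCDD replicates 2 and 3, 158 and 159 without TCDF replicates 2 and 5 and 47 with the outlier kept.

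**Figure D2:**
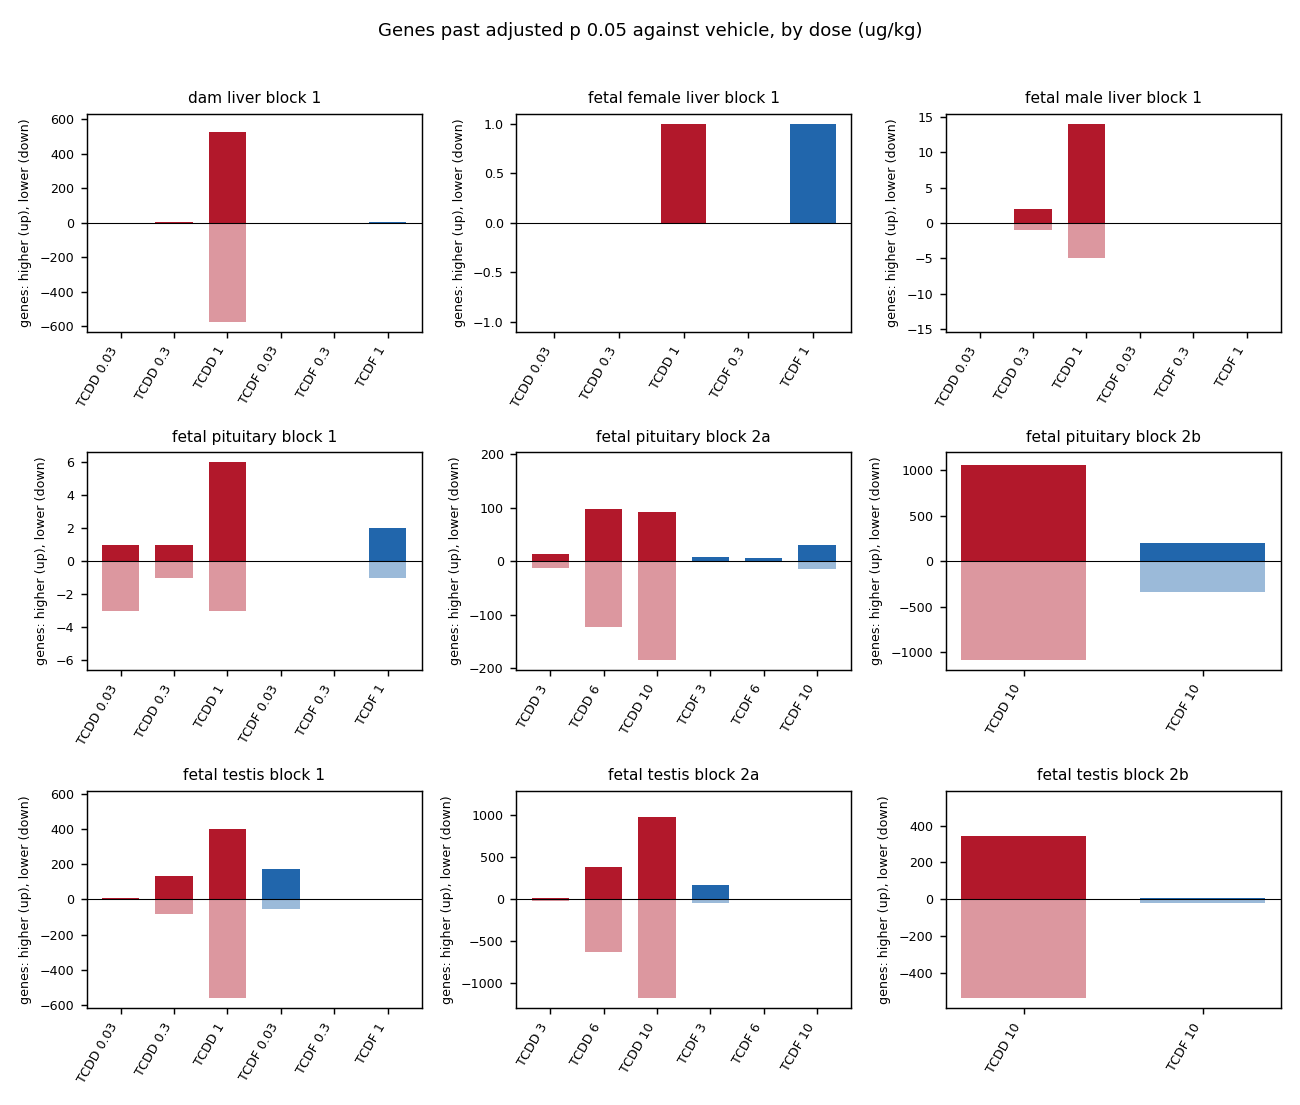
Genes called against vehicle in each organ, block and dose. Solid bars are genes that rose and pale bars genes that fell, with the highest counts at TCDD 10 in testis of block 2a (2157) and pituitary of block 2b (2150).

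Taken as a mean score, the genes that TCDD changed in block 2b testes moved the same way in testes of block 2a, which came from other litters. The response score, measured in blocks 1 and 2a, rose over vehicle by log2 0.47 (95% interval 0.34 to 0.59), 0.58 (0.44 to 0.71) and 0.69 (0.55 to 0.82) at TCDD 3, 6 and 10 (two-sided exact permutation test, p = 0.00794 each, adjusted p = 0.0476). By the same exact test the differences at TCDF 3 and 10 were 0.18 and 0.28 (p = 0.00794 each, adjusted p = 0.0476). The 0.18 at TCDF 6 did not pass adjustment (exact p = 0.0159, adjusted p = 0.0520). The score holds only genes called for TCDD, so its differences between the compounds favour TCDD by design. No TCDF score was made. TCDD exceeded TCDF at 10 by 0.41 (0.23 to 0.57, exact p = 0.00794, adjusted p = 0.0476). Its excess at 3 and 6, of 0.29 (0.14 to 0.43) and 0.40 (0.20 to 0.60), did not pass adjustment (exact p = 0.0159 each, adjusted p = 0.0520). In block 1 the score differed from vehicle by 0.33 at TCDD 1 (0.14 to 0.52, exact p = 0.0159, adjusted p = 0.0520) and 0.15 at TCDF 1 (p = 0.0476, adjusted p = 0.114), and TCDD minus TCDF at 1 was 0.17 (-0.03 to 0.38, p = 0.0794, adjusted p = 0.150), none of which passed adjustment. In pituitaries of block 2a no difference between TCDD and TCDF passed adjustment, with 0.39 at 10 (0.20 to 0.57, exact p = 0.0159, adjusted p = 0.0520), 0.085 at 3 (-0.08 to 0.25) and 0.091 at 6 (-0.10 to 0.30). Over their 2 vehicle libraries the score was higher by 0.50, 0.59 and 0.81 at TCDD 3, 6 and 10 and by 0.41, 0.50 and 0.42 at TCDF 3, 6 and 10. The exact p was 0.0476 to 0.133 (adjusted p = 0.114 to 0.211), where 2 libraries allow no p below 0.0476. With the labelled outliers kept, the differences at TCDD 3 and TCDF 10 were 0.032 and -0.059. No difference from vehicle passed the exact test at p < 0.05 in pituitaries of block 1.

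**Figure D3:**
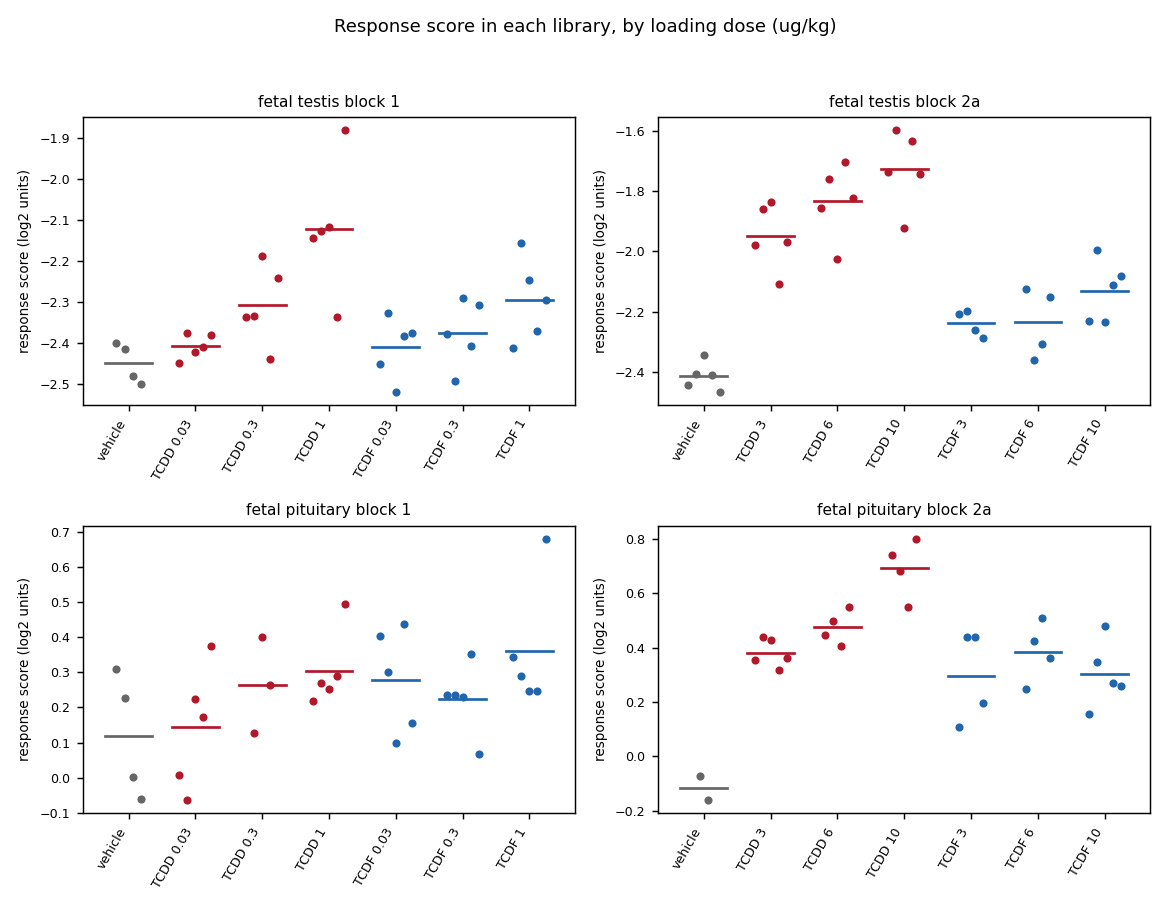
Response score of each library of blocks 1 and 2a in testis and pituitary, in log2 units, by compound and dose. At TCDD 10 testes lie 0.69 above their vehicle.

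No difference between repeated dosing and the single late dose of 10 µg/kg was called in the effect of either compound on the rising genes. For ENSRNOG00000019500, the effect in block 2a minus that in block 2b was log2 -0.78 (95% interval -2.43 to 0.88, adjusted p = 0.975) for TCDD and 0.92 (-1.15 to 2.98, adjusted p = 0.932) for TCDF in testis. In pituitary it was -1.18 (-3.21 to 0.85, adjusted p = 1) and 1.13 (-0.87 to 3.12, adjusted p = 1). For ENSRNOG00000014721 it was -0.38 (-1.03 to 0.27, adjusted p = 0.966) and 0.71 (-0.02 to 1.44, adjusted p = 0.799) in testis. In pituitary it was -1.33 (-3.89 to 1.23, adjusted p = 1) and 1.82 (-0.78 to 4.41, adjusted p = 1), and its level at TCDF 10 was 16.5 ± 4.26 CPM in block 2a and 2.81 ± 0.817 in block 2b. The difference between the compounds in this gene was smaller after repeated dosing in pituitary (log2 -3.14, -4.65 to -1.64, adjusted p = 1.14e-05). Most of these intervals leave room for differences of 4-fold and more. Over all genes, the effects differed in testis in 191 of 18034 genes for TCDD (170 higher, 21 lower after repeated dosing) and 42 for TCDF, and in pituitary in 9 of 18676 for TCDD and 94 for TCDF, all higher. Repeated dosing was given in block 2a and the single dose in block 2b, so schedule and block cannot be told apart in these counts. Without the genes of the alignment score these counts were 38, 9, 5 and 10. Without vehicle replicate 4 or 5 of block 2a the pituitary counts were 4 and 4 for TCDD and 37 and 40 for TCDF.

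ENSRNOG00000019500 was called as rising at the highest TCDD dose of every organ and block, and as it was the 1 gene called in female liver (194 in DESeq2), no other gene could be. Its smallest change was in testis of block 1, from 0.467 ± 0.163 (54 reads in 4 libraries) to 0.985 ± 0.279 CPM (log2 1.06, 95% interval 0.42 to 1.69, adjusted p = 0.0328). There it was not called with vehicle and TCDD 1 alone in the model (adjusted p = 0.0810), without vehicle replicates 2 and 3 (0.0625 and 0.144) or without TCDD 1 replicates 3 and 5 (0.0701 and 0.0897), and the other alternatives went down to 0.0319. Of the genes measured, 2910 rose in at least 1 of these 9 comparisons, 407 in at least 2, 22 in at least 4 and 1 in at least 8, and 3092 fell in at least 1, 810 in at least 2 and 31 in at least 4. The genes called at TCDD 10 in blocks 2a and 2b, which have separate vehicles, shared 142 rising and 327 falling genes in testis (18.4 and 35.9 for independent lists) and 75 rising and 130 falling in pituitary (5.79 and 11.9). TCDD 1 of block 1 and TCDD 10 of block 2a shared 76 rising and 220 falling genes in testis (22.1 and 37.7).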

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

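The tests of the 3 patterns weighed here were chosen only after the results had been seen, while the comparisons between sexes and between schedules were planned. Single libraries stood apart from their group by Dixon's test in 1 of 50 groups for gene counts, 7 of 50 for ENSRNOG00000019500 and 2 of 50 for ENSRNOG00000014721, and chance gives about 1 in 20. Gene counts were 27.7 M reads in replicate 3 of TCDD 10 in pituitary of block 2b (others 42.2 to 45.1). ENSRNOG00000019500 was 6.17 CPM in replicate 4 of TCDF 0.03 in pituitary of block 1 (others 1.31 to 2.47). In testis of block 1 it was 0.227 CPM in vehicle replicate 3 (others 0.526 to 0.583), 0.462 in replicate 4 of TCDF 1 (0.608 to 0.666) and 0.554 in replicate 3 of TCDD 0.03 (0.271 to 0.335). In fetal liver it was 0.0390 CPM in replicate 1 of male TCDD 0.3 (0.169 to 0.220), 0.0998 in replicate 3 of female TCDF 0.3 (0.0376 to 0.0396) and 0.255 in replicate 5 of female TCDD 0.03 (0 to 0.0665). ENSRNOG00000014721 was 0.743 CPM in replicate 3 of the vehicle male livers (0.464 to 0.507) and 0.0283 in replicate 5 of TCDF 0.3 in dam liver (0 in the others).

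Interaction tests called a difference in the effect of repeated and single dosing in testis (191 genes for TCDD, 42 for TCDF) and pituitary (9 for TCDD, 94 for TCDF, with 2 vehicle libraries in block 2a). Each schedule had its own block, so a difference between the blocks could give the same calls. The interaction of TCDD with fetal sex in liver called 3 genes, and 46 of 100 splits, which did not keep litters paired, called as many. Brother and sister livers share litters, and limma voom called 0 both with the litter as a block and without it, so that the change of test alone took the 3 to 0.

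The libraries that the labels deem outliers took no part in the tests, and vehicle libraries among them are left out of the vehicle levels here. ENSRNOG00000019500 lay above every analysed vehicle library in 10 of 11 dosed outliers and ENSRNOG00000014721 in 9 of 11. In pituitary of block 1 they were 23.6 and 4.19 CPM in replicate 3 of TCDD 0.3 and 23.3 and 1.83 in replicate 4 (highest vehicle 3.36 and 0.990). In pituitary of block 2a they were 123.9 and 30.2 at TCDD 6, 293 and 69.9 at TCDD 10, 40.9 and 8.45 at TCDF 3 and 29.6 and 7.24 at TCDF 6 (highest vehicle 3.15 and 1.5). In pituitary of block 2b they were 218.7 and 62.3 at TCDD 10 (2.41 and 1.22). In male liver they were 28.1 and 1.47 at TCDD 1 (0.0413 and 0.743) and ENSRNOG00000019500 was 0.0491 at TCDF 0.03, which is 1 read, as in its highest vehicle library. In female liver they were 0.344 and 0.757 at TCDD 0.3 (0.0832 and 0.576). In testis of block 2b they were not above vehicle, at 0.212 and 0.908 after TCDF 10 (0.641 and 3.47).

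The alignment score differed between whole groups of blocks 2a and 2b, vehicle groups included. An effect of the compounds as the whole cause is excluded by the vehicle testes, whose score was 0.68 higher in block 2b than in block 2a (two-sided exact permutation test, p = 0.00794, n = 5 each), while TCDD 10 lay 1.03 above its vehicle in block 2a and -0.43 from it in block 2b. RNA of dam liver, fetal liver or pituitary is excluded as the cause in the testes of block 2a at TCDF 3, because genes higher in these organs differed from vehicle by medians of log2 -0.051 to 0.045 there (MAD at most 0.300), where the score genes moved by 1.03. Other organs and other groups were not tested for this. A difference between sequencing or library runs may be the source and stays open. Within groups of blocks 2a and 2b the score did not follow the share of unaligned reads past the threshold, in testis (Pearson r = 0.0671, Spearman rho = 0.119, 47 libraries, permutation p = 0.674) or pituitary (r = -0.255, rho = -0.309, 42 libraries, p = 0.164, adjusted p = 0.204), but the score hardly varied there (SD within groups 0.0591 and 0.107). In block 1, where it varied more, it followed that share in testis (r = 0.930, rho = 0.934, 34 libraries, p = 1e-05, the smallest 100000 permutations can give, adjusted p = 5e-05, r = 0.917 without the 2 farthest libraries) and dam liver (r = 0.837, rho = 0.763, 35 libraries, p = 7e-05, adjusted p = 0.000175, r = 0.784 without 2), and in pituitary r was 0.289 (rho = 0.306, 32 libraries, p = 0.141). As the labels name no runs, this explanation and an unrecorded difference between litters or dissections cannot be told apart.

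Testes of block 1 gave 228 called genes at the lowest TCDF dose against 4 and 0 at the higher ones. The alignment score as the whole cause is excluded, since the 228 genes differed from vehicle by a median of log2 0.286 (MAD 0.118) in their own directions and by 0.289 (MAD 0.124) with the score as a covariate, where 136 genes were called, 129 of them among the 228. A vehicle group that stood apart from every dosed group may be the source. Each of the 7 groups was set against the mean of the other 6 over all genes, which called 725 genes for the vehicle, 0, 32 and 16 for TCDD 0.03, 0.3 and 1 and 0 for each TCDF dose (in edgeR, with 594 at unadjusted p < 0.05 for TCDD 0.03 and 1713, 774 and 537 for TCDF 0.03, 0.3 and 1, not run in DESeq2). The same vehicle group underlies the 216 and 960 genes at TCDD 0.3 and 1. A response shared by all doses would set the vehicle apart as well and was not told from a vehicle group that differs for another reason. The count at TCDF 0.03 fell to 1 and 0 without vehicle replicates 2 and 3.

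In pituitary the difference between TCDD and TCDF in ENSRNOG00000019500 was smaller after repeated than after single dosing, by log2 -2.31 (95% interval -3.70 to -0.92, adjusted p = 1.51e-05), and in ENSRNOG00000014721 by -3.14 (adjusted p = 1.14e-05). In testis these contrasts were -1.69 (adjusted p = 0.315) and -1.09 (adjusted p = 0.0412). Faster loss of TCDF than of TCDD may be the cause, as tissue was taken 30 minutes after the last of the repeated doses and days after the single dose, but repeated dosing also gave TCDF 10 times the maintenance dose, so the -2.31 cannot separate these. The alignment score as the whole cause stays open for ENSRNOG00000019500 in pituitary, where the score genes moved by a median of -0.70 (MAD 0.472) in the same contrast. For ENSRNOG00000014721 that -0.70 with its MAD falls well short of the -3.14, and in testis the score genes moved the other way, by 0.709 (MAD 0.500). These values argue against the score as the whole cause for that gene. They do not exclude it, because the median of other genes does not limit how far 1 gene can move.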

How the results depend on the processing

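The alternatives with the alignment score, limma voom without the litter block, and all tests of the response score, were chosen only after the results had been seen. Of 60 counts of called genes, 58 stayed within 1.5 times of their value with median-of-ratios size factors, 52 without the filter on low counts, 20 in DESeq2, 48 without the genes of the alignment score and 31 with that score as a covariate. So did 23 of 45 with vehicle and 1 dose alone in the model, 23 of 39 with the labelled outliers kept and 514 of 723 values with 1 replicate left out. Of 295 log2 differences of the 4 printed genes, the same direction and side of the threshold held for 294, 292, 277, 293 and 253 under the first 5 of these, for 142 of 154, 185 of 196 and 2684 of 2898 under the others. The response score kept both in 36 of 36 comparisons with median-of-ratios size factors, 35 without the filter and 29 with the outliers kept. Unless a cause is named below, the cause was not tested.

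Median-of-ratios size factors took male liver at TCDD 1 from 19 to 3 and testis of block 1 at TCDF 0.3 from 4 to 0. Dropping the filter took male liver at TCDD 1 from 19 to 4. It took pituitary of block 1 at TCDD 0.03 from 4 to 1 and at TCDD 1 from 9 to 5. Dropping the filter took testis of block 1 at TCDD 0.03 from 12 to 0, at TCDD 0.3 from 216 to 86, at TCDF 0.03 from 228 to 89 and at TCDF 0.3 from 4 to 0. Dropping the filter took the comparison of the sexes for TCDD from 3 to 1. All 8 counts that moved without the filter fell.

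DESeq2 took dam liver at TCDD 0.03 from 1 to 5, at TCDD 0.3 from 5 to 35, at TCDF 0.03 from 0 to 1, at TCDF 0.3 from 2 to 6, at TCDF 1 from 3 to 6 and between the compounds from 223 to 544. DESeq2 took female liver at TCDD 0.3 from 0 to 1, at TCDD 1 from 1 to 194, at TCDF 0.3 from 0 to 1, at TCDF 1 from 1 to 5 and between the compounds from 1 to 0. DESeq2 took male liver at TCDD 1 from 19 to 198, at TCDF 1 from 0 to 1 and between the compounds from 2 to 5. DESeq2 took pituitary of block 1 at TCDD 0.3 from 2 to 15, at TCDD 1 from 9 to 25, at TCDF 0.03 from 0 to 1 and between the compounds from 2 to 8. DESeq2 took pituitary of block 2a at TCDD 3 from 25 to 53, at TCDD 6 from 222 to 415, at TCDD 10 from 277 to 457, at TCDF 3 from 10 to 19, at TCDF 6 from 6 to 41, at TCDF 10 from 44 to 122 and between the compounds from 432 to 848. DESeq2 took pituitary of block 2b at TCDF 10 from 547 to 1507. DESeq2 took testis of block 1 at TCDD 0.03 from 12 to 79, at TCDD 0.3 from 216 to 678, at TCDD 1 from 960 to 1639, at TCDF 0.03 from 228 to 980, at TCDF 0.3 from 4 to 71, at TCDF 1 from 0 to 43 and between the compounds from 19 to 45. DESeq2 took testis of block 2a at TCDD 3 from 35 to 61, at TCDF 6 from 1 to 55 and at TCDF 10 from 16 to 125. DESeq2 took testis of block 2b at TCDF 10 from 25 to 50 and between the compounds from 276 to 477. DESeq2 took the comparison of the sexes for TCDF from 0 to 1 and of dosing schedules for TCDD in pituitary from 9 to 23. Of the 40 counts that moved in DESeq2, 39 rose.

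Single-dose models took dam liver at TCDD 0.3 from 5 to 3 and at TCDD 1 from 1100 to 306. Single-dose models took female liver at TCDD 1 from 1 to 2 and at TCDF 1 from 1 to 12. Single-dose models took male liver at TCDD 0.3 from 3 to 0, at TCDD 1 from 19 to 1 and at TCDF 1 from 0 to 1. Single-dose models took pituitary of block 1 at TCDD 0.03 from 4 to 0, at TCDD 0.3 from 2 to 0 and at TCDF 1 from 3 to 0. Single-dose models took pituitary of block 2a at TCDD 6 from 222 to 55, at TCDD 10 from 277 to 468, at TCDF 3 from 10 to 2, at TCDF 6 from 6 to 18 and at TCDF 10 from 44 to 16. Single-dose models took testis of block 1 at TCDD 0.03 from 12 to 0, at TCDD 0.3 from 216 to 3, at TCDD 1 from 960 to 96, at TCDF 0.03 from 228 to 437 and at TCDF 0.3 from 4 to 2. Single-dose models took testis of block 2a at TCDD 3 from 35 to 14 and at TCDF 6 from 1 to 0. Keeping outliers took female liver at TCDD 0.3 from 0 to 48. Keeping outliers took male liver at TCDD 1 from 19 to 111 and between the compounds from 2 to 6. Keeping outliers took pituitary of block 1 at TCDD 0.3 from 2 to 63 and between the compounds from 2 to 20. Keeping outliers took pituitary of block 2a at TCDD 3 from 25 to 274, at TCDD 6 from 222 to 1231, at TCDF 3 from 10 to 35, at TCDF 6 from 6 to 81, at TCDF 10 from 44 to 270 and between the compounds from 432 to 184. Keeping outliers took pituitary of block 2b at TCDF 10 from 547 to 126. Keeping outliers took testis of block 2b at TCDD 10 from 879 to 71, at TCDF 10 from 25 to 13 and between the compounds from 276 to 47. Keeping outliers took the comparison of the sexes for TCDD from 3 to 203. Limma voom with the litter block and without it took the comparison of the sexes for TCDD from 3 to 0.

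Dropping score genes took dam liver between the compounds from 223 to 92 and male liver at TCDD 1 from 19 to 3. Dropping score genes took pituitary of block 2a at TCDF 10 from 44 to 17 and between the compounds from 432 to 280. Dropping score genes took testis of block 2a at TCDF 3 from 208 to 44, at TCDF 6 from 1 to 0 and at TCDF 10 from 16 to 7. Dropping score genes took testis of block 2b at TCDF 10 from 25 to 8. Dropping score genes took the comparison of dosing schedules for TCDD in testis from 191 to 38, for TCDF in testis from 42 to 9, for TCDD in pituitary from 9 to 5 and for TCDF in pituitary from 94 to 10. In male liver 0 of the 19 called genes belonged to the score, so no called gene was itself left out there.

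The covariate took dam liver at TCDD 0.3 from 5 to 3, at TCDD 1 from 1100 to 29 and between the compounds from 223 to 13. It took male liver at TCDD 1 from 19 to 5. The covariate took pituitary of block 1 at TCDD 0.03 from 4 to 1 and at TCDD 1 from 9 to 5. The covariate took pituitary of block 2a at TCDD 6 from 222 to 1447, at TCDF 3 from 10 to 6, at TCDF 6 from 6 to 13, at TCDF 10 from 44 to 1079 and between the compounds from 432 to 2381. The covariate took pituitary of block 2b at TCDD 10 from 2150 to 20, at TCDF 10 from 547 to 17 and between the compounds from 574 to 53. The covariate took testis of block 1 at TCDD 0.3 from 216 to 88, at TCDF 0.03 from 228 to 136 and at TCDF 0.3 from 4 to 0. The covariate took testis of block 2a at TCDD 3 from 35 to 130, at TCDD 6 from 1008 to 2652, at TCDF 3 from 208 to 2377, at TCDF 6 from 1 to 1954, at TCDF 10 from 16 to 1038 and between the compounds from 1295 to 3055. The covariate took testis of block 2b at TCDD 10 from 879 to 10 and at TCDF 10 from 25 to 0. The covariate took the comparison of dosing schedules for TCDD in testis from 191 to 3945, for TCDF in testis from 42 to 1877, for TCDD in pituitary from 9 to 2108 and for TCDF in pituitary from 94 to 2720. The covariate could not be told from the groups in blocks 2a and 2b, where the spread of the score within groups was 0.137 to 0.233 times that between group means, and the adjustment extrapolated. In dam liver this ratio was 0.761, and in the other organs of block 1 it was 2.05 to 3.44. It also reversed TCDD minus TCDF at 3 in testis of block 2a for ENSRNOG00000019500 (log2 2.93 to -0.37) and ENSRNOG00000014721 (log2 1.52 to -0.44).

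Leaving out 1 replicate at a time moved at least 1 count by over 1.5 times in these comparisons, given with the reported count and the range. Leave-one-out took dam liver at TCDD 0.3 (5) to between 3 and 6, at TCDD 1 (1100) to between 366 and 1198 and between the compounds (223) to between 71 and 571. Leave-one-out took female liver at TCDD 0.03 (0) to between 0 and 2, at TCDD 0.3 (0) to between 0 and 16, at TCDD 1 (1) to between 1 and 95, at TCDF 1 (1) to between 0 and 4 and between the compounds (1) to between 1 and 7. Leave-one-out took male liver at TCDD 0.03 (0) to between 0 and 1, at TCDD 0.3 (3) to between 0 and 5, at TCDD 1 (19) to between 2 and 144 and between the compounds (2) to between 1 and 10. Leave-one-out took pituitary of block 1 at TCDD 0.03 (4) to between 1 and 9, at TCDD 0.3 (2) to between 0 and 10, at TCDD 1 (9) to between 4 and 32, at TCDF 0.03 (0) to between 0 and 3, at TCDF 0.3 (0) to between 0 and 5 and between the compounds (2) to between 2 and 6. Leave-one-out took pituitary of block 2a at TCDD 3 (25) to between 3 and 23, at TCDD 6 (222) to between 24 and 360, at TCDD 10 (277) to between 27 and 476, at TCDF 3 (10) to between 0 and 9, at TCDF 6 (6) to between 0 and 10 and at TCDF 10 (44) to between 5 and 61. Leave-one-out took pituitary of block 2b at TCDD 10 (2150) to between 1290 and 2120 and at TCDF 10 (547) to between 50 and 2172. Leave-one-out took testis of block 1 at TCDD 0.03 (12) to between 0 and 9, at TCDD 0.3 (216) to between 7 and 731, at TCDD 1 (960) to between 186 and 1415, at TCDF 0.03 (228) to between 0 and 551, at TCDF 0.3 (4) to between 0 and 12 and at TCDF 1 (0) to between 0 and 10. Leave-one-out took testis of block 2a at TCDD 3 (35) to between 13 and 64, at TCDD 6 (1008) to between 627 and 968, at TCDD 10 (2157) to between 1395 and 2431, at TCDF 6 (1) to between 0 and 2 and at TCDF 10 (16) to between 0 and 24. Leave-one-out took testis of block 2b at TCDD 10 (879) to between 585 and 928, at TCDF 10 (25) to between 16 and 26 and between the compounds (276) to between 158 and 227. Leave-one-out took the comparison of the sexes for TCDD (3) to between 1 and 12 and for TCDF (0) to between 0 and 1. Leave-one-out took the comparison of dosing schedules for TCDD in pituitary (9) to between 4 and 10 and for TCDF in pituitary (94) to between 37 and 97.

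Without the filter the response score went in testis of block 1 TCDD 0.3 minus vehicle from 0.14 to 0.15 (exact p = 0.0635). Kept outliers took the response score in testis of block 1 TCDD 0.03 minus vehicle from 0.042 to -0.035 (exact p = 0.381), TCDD 0.3 minus vehicle from 0.14 to 0.070 (exact p = 0.389), TCDF 1 minus vehicle from 0.15 to 0.18 (exact p = 0.230) and TCDD minus TCDF at 0.03 from 0.003 to -0.078 (exact p = 0.0714). Testis of block 1 held no labelled outlier. With outliers kept, the genes of the score were chosen anew in block 2b with its outlier, so these changes reflect another set of genes. Kept outliers took the response score in pituitary of block 1 TCDD 0.03 minus vehicle from 0.025 to 0 (exact p = 1). Kept outliers took the response score in pituitary of block 2a TCDD 3 minus vehicle from 0.50 to 0.032 (exact p = 0.976) and TCDF 10 minus vehicle from 0.42 to -0.059 (exact p = 0.929). Leave-one-out moved a call or the sign of the response score in testis of block 1 for TCDD 0.3 minus vehicle (0.11 to 0.17), TCDF 1 minus vehicle (0.12 to 0.18), TCDD minus TCDF at 0.03 (-0.024 to 0.025) and TCDD minus TCDF at 1 (0.11 to 0.23), as lowest and highest values. It did so in testis of block 2a for TCDF 6 minus vehicle (0.14 to 0.22). In pituitary of block 1 it did so for TCDD 0.03 minus vehicle (-0.035 to 0.088) and TCDD 1 minus vehicle (0.13 to 0.25). It did for TCDF 1 minus vehicle (0.16 to 0.30), and for TCDD minus TCDF at 0.3 (-0.029 to 0.11) and 1 (-0.10 to 0.023). In pituitary of block 2a it did so for TCDD 3 minus vehicle (0.48 to 0.51) and TCDF 10 minus vehicle (0.37 to 0.46). A smaller group raises the smallest p that the exact test can give, which alone ended the calls in pituitary of block 2a.

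Counting limits how well a rise from near absence can be sized. Vehicle groups of fetal liver held 6 (female) and 3 (male) reads of ENSRNOG00000019500 in 4 libraries each. The counting intervals cover this error only. They leave out the spread between livers, which at TCDD 1 ran from 8.38 to 31.9 CPM in females and from 6.20 to 94.96 CPM in males. No alternative varied the depth.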

Other observations

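The tests of genes grouped by organ were chosen only after the results had been seen, and the splits of the libraries were planned. Genes at least 8-fold higher in dam liver than in the other organs (130) lay, as a group, above their vehicle level in fetal livers of both sexes at dose 1 by camera at its preset correlation. The medians of the measured ones were log2 0.35 at TCDD 1 (adjusted p = 0.000261, with an estimated correlation 0.505) and 0.55 at TCDF 1 (adjusted p = 2.34e-13, with an estimated correlation 0.0852) in females, and 0.58 at TCDD 1 (adjusted p = 1.11e-11, with an estimated correlation 0.258) and 0.38 at TCDF 1 (adjusted p = 1.33e-12, with an estimated correlation 0.219) in males. No single gene of this group was called by edgeR in these 4 comparisons. Camera also called other groups in these livers, in which 0 or 1 genes were called by edgeR: genes higher in pituitary in females at TCDD 1 (median 0.218, adjusted p = 0.00296, with an estimated correlation 0.505) and TCDF 1 (0.185, 0.0108, with it 0.502), genes higher in both livers in females at TCDF 1 (0.234, 2.67e-20, with it 0.0852) and in males at TCDD 1 (0.181, 2.50e-10, with it 0.447) and TCDF 1 (0.146, 1.33e-12, with it 0.338), and genes higher in fetal liver in females at TCDD 1 (-0.064, 0.0455, with it 0.505) and TCDF 1 (-0.094, 0.000714, with it 0.167). Of 499 genes higher in pituitary than in the other organs, 34 fell and 5 rose at TCDD 10 in pituitary of block 2a (camera adjusted p = 0.00909, with an estimated correlation 0.395), where 185 fell and 92 rose of all 18320 genes. In block 2b, with 5 vehicle libraries and not 2, 71 of the 499 fell and 74 rose (adjusted p = 0.447). No call of camera in any organ held with an estimated correlation.

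The 52 counts of called genes from groups of at least 3 libraries were set against other splits of the same libraries into groups of the same sizes, the real split included. The 6 dose comparisons and 2 comparisons of schedules that use the 2 vehicle pituitaries of block 2a were not split. The limit of 1 in 20 was not adjusted for the 52 comparisons, so that shares of 2 to 4 of 100 are weak evidence, as for the 3 genes in male liver at TCDD 0.3, which were 0 in the single-dose model and 0 without any of 4 libraries. The splits excluded chance in dam liver at TCDD 0.03 (1 gene, highest other 1, 3 of 100 splits as large), at TCDD 0.3 (5 genes, highest other 1, 1 of 100 splits as large), at TCDD 1 (1100 genes, highest other 506, 1 of 100 splits as large), at TCDF 1 (3 genes, highest other 1, 1 of 100 splits as large) and between the compounds (223 genes, highest other 147, 1 of 100 splits as large). The splits excluded chance in male liver at TCDD 0.3 (3 genes, highest other 14, 2 of 100 splits as large) and between the compounds (2 genes, highest other 4, 4 of 100 splits as large). The splits excluded chance in pituitary of block 2a between the compounds (432 genes, highest other 39, 1 of 100 splits as large). Chance was excluded in pituitary of block 2b at TCDD 10 (2150 genes, highest other 799, 1 of 100 splits as large), at TCDF 10 (547 genes, highest other 1284, 2 of 100 splits as large) and between the compounds (574 genes, highest other 420, 1 of 100 splits as large). The splits excluded chance in testis of block 1 at TCDD 0.03 (12 genes, highest other 82, 3 of 100 splits as large), at TCDD 0.3 (216 genes, highest other 745, 4 of 100 splits as large), at TCDD 1 (960 genes, highest other 236, 1 of 100 splits as large), at TCDF 0.03 (228 genes, highest other 2, 1 of 100 splits as large), at TCDF 0.3 (4 genes, highest other 0, 1 of 100 splits as large) and between the compounds (19 genes, highest other 6, 1 of 100 splits as large). Chance was excluded in testis of block 2a at TCDD 3 (35 genes, highest other 46, 2 of 100 splits as large), at TCDD 6 (1008 genes, highest other 357, 1 of 100 splits as large), at TCDD 10 (2157 genes, highest other 1399, 1 of 100 splits as large), at TCDF 3 (208 genes, highest other 105, 1 of 100 splits as large), at TCDF 10 (16 genes, highest other 5, 1 of 100 splits as large) and between the compounds (1295 genes, highest other 97, 1 of 100 splits as large). The splits excluded chance in testis of block 2b at TCDD 10 (879 genes, highest other 149, 1 of 100 splits as large), at TCDF 10 (25 genes, highest other 498, 2 of 100 splits as large) and between the compounds (276 genes, highest other 9, 1 of 100 splits as large). For dosing schedules in testis the splits cannot exclude chance, because mixing treated and vehicle libraries also removes the compound's own effect. As many genes were called in 2 of 100 for TCDD (191, highest other 220) and 1 of 100 for TCDF (42, highest other 22).

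Chance was not excluded in dam liver at TCDF 0.03 (0 genes, highest other 3, 100 of 100 splits as large) and at TCDF 0.3 (2 genes, highest other 286, 7 of 100 splits as large). Other splits left chance open in female liver at TCDD 0.03 (0 genes, highest other 1, 100 of 100 splits as large), at TCDD 0.3 (0 genes, highest other 12, 35 of 35 splits as large), at TCDD 1 (1 gene, highest other 3, 4 of 35 splits as large), at TCDF 0.3 (0 genes, highest other 0, 35 of 35 splits as large), at TCDF 1 (1 gene, highest other 4, 11 of 35 splits as large) and between the compounds (1 gene, highest other 104, 28 of 100 splits as large). The splits did not exclude chance in male liver at TCDD 0.03 (0 genes, highest other 16, 100 of 100 splits as large), at TCDD 1 (19 genes, highest other 116, 3 of 35 splits as large), at TCDF 0.03 (0 genes, highest other 2, 35 of 35 splits as large), at TCDF 0.3 (0 genes, highest other 12, 100 of 100 splits as large) and at TCDF 1 (0 genes, highest other 1, 100 of 100 splits as large). Chance was not excluded in pituitary of block 1 at TCDD 0.03 (4 genes, highest other 89, 33 of 100 splits as large), at TCDD 0.3 (2 genes, highest other 2305, 15 of 35 splits as large), at TCDD 1 (9 genes, highest other 88, 6 of 100 splits as large), at TCDF 0.03 (0 genes, highest other 1140, 100 of 100 splits as large), at TCDF 0.3 (0 genes, highest other 1698, 100 of 100 splits as large), at TCDF 1 (3 genes, highest other 2124, 32 of 100 splits as large) and between the compounds (2 genes, highest other 222, 12 of 100 splits as large). Other splits left chance open in testis of block 1 at TCDF 1 (0 genes, highest other 34, 100 of 100 splits as large). The same held in testis of block 2a at TCDF 6 (1 gene, highest other 5, 7 of 100 splits as large). Chance was not excluded in the comparison of the sexes for TCDD (3 genes, highest other 65, 46 of 100 splits as large) and for TCDF (0 genes, highest other 22, 100 of 100 splits as large). These splits test the number of called genes and not the level of 1 gene. ENSRNOG00000019500 lay above every vehicle library in each treated library of 7 comparisons that called it and whose count left chance open. At the highest doses this separation was part of the rule that chose the ID, so it is no independent evidence against chance there. It was 14.4 to 102.5 CPM in dam liver at TCDF 0.3 (vehicle at most 0.414), 8.38 to 31.9 at TCDD 1 and 0.595 to 3.57 at TCDF 1 in female liver (0.0832), 6.20 to 94.96 at TCDD 1 in male liver (0.0413), and 10.9 to 17.4 at TCDD 0.3, 43.1 to 66.6 at TCDD 1 and 15.4 to 27.0 at TCDF 1 in pituitary of block 1 (3.36).

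Several other splits called more than 3 times the real count in dam liver at TCDF 0.3 and the comparison of the sexes for TCDD. They did so in pituitary of block 1 at TCDD 0.03, 0.3 and 1 and at TCDF 1. This points to a structure of the samples that was not tested. Where the real count was 0, several other splits called more than 3 genes in female liver at TCDD 0.3, male liver at TCDD 0.03, pituitary of block 1 at TCDF 0.03, pituitary of block 1 at TCDF 0.3, testis of block 1 at TCDF 1 and the comparison of the sexes for TCDF.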
